A study of Mus musculus with 6 samples.

How the data were processed

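RNA was measured by sequencing in CD8+ T cells sorted from MC38 tumours, a mouse colon carcinoma line grown on C57BL/6 mice. The 6 samples fall into 2 groups of 3 by their treatment label, PBS or αPD-1-IL-15-R. The labels do not say whether each sample came from its own mouse or from a pool, so the p-values given here measure only the spread between these samples, which may be partly technical. Cells were sorted on a BD Aria III and RNA and libraries were made by BGI, per the labels' protocols.

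The authors deposited 1 table of genes, with values for each of the 6 samples and the result of their own comparison. Its read counts are estimated counts per gene, which need not be whole and were not scaled by the authors; between 88.7% and 90.1% of them were whole numbers in each library. The TPM and FPKM columns were computed by the authors, per the file headers, and the TPM of the table's genes sum to between 57.8% and 65.1% of a library's full TPM total. The log10 columns hold log10(TPM + 1) of the deposited TPM values, and recomputing them differed by at most 8.9e-16. The log2 fold change, the p-value and the q-value of treated over control are the authors' own, per the file headers, and the test behind them is not given in the sources used here. Other values came from a small deposited notes sheet, in which the authors give a log2 change, a p-value and a q-value for Havcr2 and Stat5a. The submitters' processing notes name HISAT2 and RSEM, with neither role nor version. The genome build is not given in the sources used here, so no coordinates are printed. Of the table's numeric gene identifiers, 6453 matched a RefSeq gene table and 6452 of these carried the same symbol.

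The table is a selection made by the authors: its 6467 genes, all marked as mRNA, have q-values up to 0.0499. Benjamini-Hochberg adjustment of the deposited p-values over 17077 genes returned 100.0% of the deposited q-values within 1e-06, the largest difference being 7.5e-16. The table was therefore read as every gene below a q-value of 0.05 among 17077 tested, or 37.9% of them. A gene outside it either had a q-value of 0.05 or more or was not tested. No level or change is given here for such a gene, apart from those of the notes sheet. The authors' size factors were recovered by fitting the deposited log2 changes of 3105 genes with more than 200 reads in every library, with a median residual of 0.00010 on the log2 scale. They were 1.08, 1.03 and 1.04 in the PBS libraries and 1.01, 0.91 and 0.94 in the treated libraries.

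Normalised read counts are the deposited counts divided by these size factors, averaged as mean ± SD over 3 libraries. Counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr, robust quasi-likelihood fit and test, two-sided, group as the only term), with the authors' size factors as scaling. P-values were adjusted by Benjamini-Hochberg over the 17077 genes the authors tested, and genes under 0.05 were called. The plan written before the data were examined was TMM scaling of a table of all genes. The authors' scaling and the number of genes in the adjustment were chosen after the table proved to be a selection and after counts of calls under several scalings had been seen. The SE of a log2 change is its size divided by the square root of the F statistic. Every gene passing the edgeR fit had already passed the authors' threshold, so the counts of calls describe genes picked on these libraries.

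The fit was tested on simulated counts for 6193 genes, of which 200 were changed, with the means, dispersions and scaling of this comparison. It recovered 1% of the genes changed by 1 on the log2 scale and 27% of those changed by 2. Only 200 genes differed there, against the 6467 of the authors' table, and adjustment over 17077 genes is stricter when few genes differ. These shares are therefore not the power of the real fit, which called 2327 genes. Of 30 calls, 2 were unchanged genes (6.7%). The biological coefficient of variation of the real libraries was 0.366.

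Before the data were examined, 37 gene lists were fixed, covering T cell functions, metabolism, cell division, sample handling and other cell types. For each list, the text gives how many members were higher or lower in the authors' deposited table, and how many passed the edgeR fit. The planned set tests, which need all genes, were not run. In their place, and chosen after the table was seen to be a selection, a two-sided Fisher's exact test compared the members higher and lower with the other table genes, for the 29 lists with at least 5 members in the table, adjusted by Benjamini-Hochberg. Genes of a list are not independent, so these p-values are too small by an unknown amount. List medians per library use log2(normalised count + 0.5) relative to the PBS mean. Exact permutation tests of 3 against 3 libraries cannot go below p = 0.10.

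Named genes follow a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap and whose mean is at least 5 CPM, leaving out unnamed gene models, pseudogenes and antigen receptor segments. It adds up to 4 members of each list, the 2 with the smallest adjusted p that rose and the 2 that fell, ranked here by the authors' q-values. It always includes Cd8a, Cd8b1, Cd3e, Pdcd1, Il2rb, Il2rg, Il15ra, Gzmb, Ifng, Mki67, Tcf7 and Cish. A gene named outside the rule was chosen after its values were seen, and is said to be. The values of 1 gene that the rule names are not reported here.

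Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), median-ratio factors of the table's genes, library size only (relative sizes from count divided by FPKM), no filter, a mean of at least 5 CPM, a test against a fold of 1.5, the sample number as a block, and leaving out each library in turn. The plan gave DESeq2 and limma-voom their own scaling; after the table was seen they were run with the authors' size factors instead, so that only the test changed. Alternatives added after the data were seen were TMM over the table's genes, scaling on the T cell receptor signalling list, and adjustment over the table's genes only. List tests, permutations and plots used Python 3.11.15 with SciPy 1.17.1, statsmodels 0.14.6 and pandas 2.3.3. Reads within the table numbered between 8484736 and 9403710 per library. The total depth of the libraries is not known from the table.

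Chi-square statistics between libraries of 1 group, divided by their degrees of freedom, ranged from 6.9 to 139.7, so no pair agreed within sampling noise and each library was counted once.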

Results

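The data comprise RNA-seq of tumour-infiltrating CD8+ T cells from mice bearing MC38 tumours, a mouse colon carcinoma line. Of the 6 libraries, 3 came from mice given PBS and 3 from mice given αPD-1-IL-15-R, an anti-PD-1 antibody that carries concealed IL-15, per the study's title. The dose was 30 µg by intraperitoneal injection on days 14 and 17, and cells were taken 48 hours after the later injection. The genes analysed held 9248214, 8484736 and 8550029 reads in PBS libraries 1 to 3 and 9403710, 8888357 and 8886351 reads in treated libraries 1 to 3. These are the 6467 genes that passed the authors' own threshold, 2734 of them higher and 3733 lower in the treated libraries.

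The single comparison, treated against PBS, asks how the RNA of CD8+ T cells sorted from the tumour differs after αPD-1-IL-15-R. No group was given anti-PD-1 or IL-15 alone, so the effects of these parts cannot be told apart. Granzyme genes, which encode the serine proteases of cytotoxic granules, and receptors of the natural killer (NK) cell type were mostly higher. Gzmg rose 15.3-fold, from 126 ± 52.8 to 1921 ± 202 normalised reads (SD, n = 3), and Klrb1c, which encodes the receptor NK1.1, rose 14.2-fold, from 197 ± 94.6 to 2798 ± 401 (SD, n = 3). Genes of antigen-presenting and stromal cells were mostly lower. Cd74, the invariant chain of MHC class II, fell 5.9-fold, from 16207 ± 1917 to 2735 ± 1488 (SD, n = 3), and Fn1, the matrix protein fibronectin, fell 8.3-fold, from 19287 ± 3921 to 2308 ± 1636 (SD, n = 3), a log2 change of -3.06 that was -3.82 without treated library 1.

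The 10 largest rises by the fixed rule were Gzmg, Klra5, Klrb1c, Gzma, Hemgn, Tuba8, Gzmf, Cdkn2b, Klra1 and Dsc2. Their log2 changes ran from 3.94 (SE 0.37) for Gzmg to 3.08 (SE 0.53) for Dsc2, and the edgeR adjusted p was 0.04 for each. Gzmf, at 74512 ± 18743 normalised reads in the treated libraries (SD, n = 3), had the most reads of these, against 6994 ± 3502 in PBS. The cell cycle inhibitor gene Cdkn2b rose from 13.4 ± 5.4 to 132 ± 8.9 reads (SD, n = 3). The 10 largest falls were Fcrls, Clu, Ly6d, Cd248, Adam11, Ccdc24, Igfbp3, Hoxd4, Cxcl14 and Zfp423, with log2 changes from -4.16 (SE 0.48) for Fcrls to -3.63 (SE 0.66) for Zfp423. Cd248, a marker of stromal fibroblasts and pericytes, fell from 174 ± 39.0 to 12.1 ± 13.5 reads, with an edgeR adjusted p of 0.045. Clu, the secreted chaperone clusterin, fell from 416 ± 144 to 24.8 ± 29.9 reads (edgeR adjusted p = 0.048). Some of these values depended on treated library 1: without it, the log2 changes were -5.76 for Clu, -5.29 for Cd248, -5.12 for Ccdc24, -4.40 for Hoxd4 and -4.32 for Zfp423, against -4.05, -3.82, -3.67, -3.65 and -3.63 with it.

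**Figure D1:**
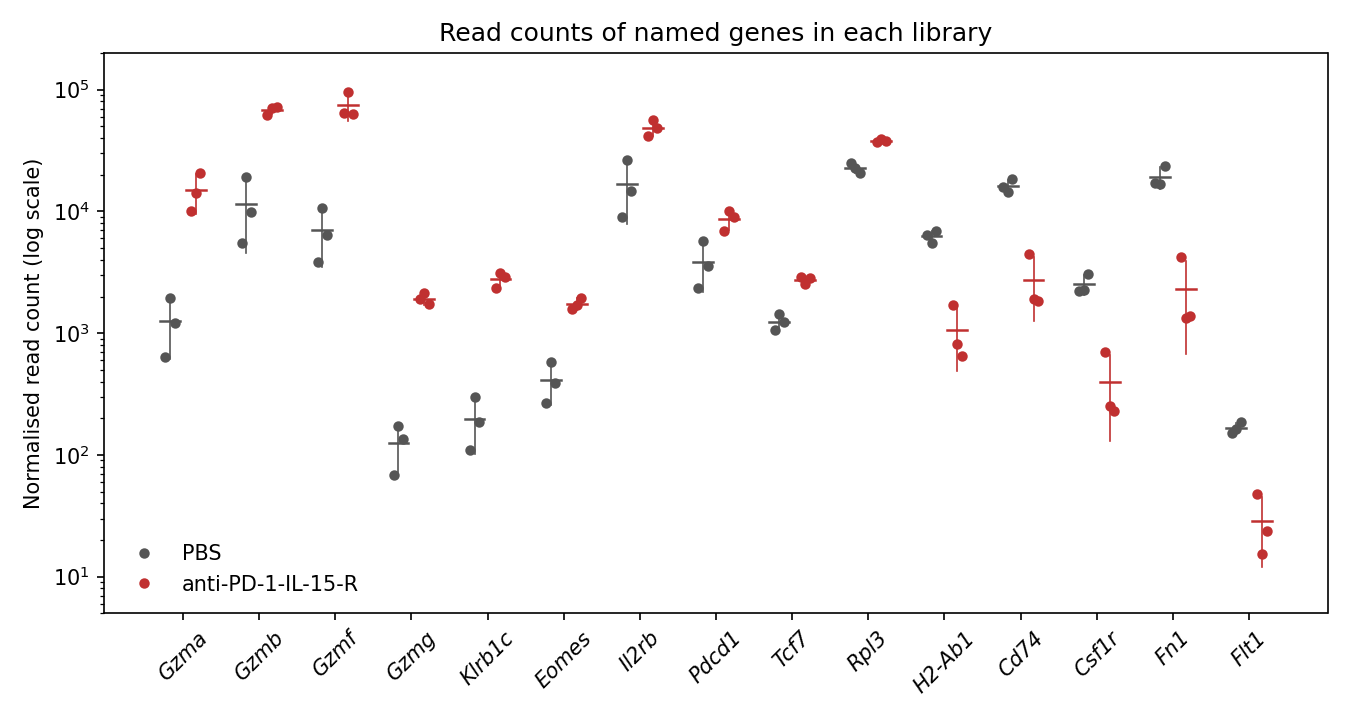
Normalised read counts (log scale) of 15 named genes in each library, with PBS in grey and αPD-1-IL-15-R in red; points are libraries, horizontal bars group means and vertical bars the SD of 3 libraries. The granzyme genes sat higher in all 3 treated libraries, with Gzmb at 68153 against 11490 reads on average, and Cd74, Csf1r, Fn1 and Flt1 sat lower.

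Most cytotoxic genes were higher. In the authors' deposited table, 19 of the 20 cytotoxic effector genes present were higher, with a median log2 change of 1.52, a split that differed from that of the other table genes (Fisher's exact test, adjusted p = 6.6e-06). The edgeR fit called 9 of them, all higher, and 20 when adjusted over the list alone. Gzma rose from 1263 ± 652 to 14968 ± 5461 reads, Gzmb by 2.57 (SE 0.47) on the log2 scale with an edgeR adjusted p of 0.041, and Csf2, the gene of the cytokine GM-CSF, by 1.58 (SE 0.22) with an edgeR adjusted p of 0.04. Lamp1, a lysosomal membrane protein that reaches the surface on degranulation, was the exception at a log2 change of -1.01 (SE 0.24), just short of the edgeR threshold. All 9 granzyme genes were higher under each scaling tried, by a median of 2.55 with the authors' scaling and 1.39 when scaled on the T cell receptor signalling genes. That scaling took the median of the whole list to 0.31 and of its 11 genes other than granzymes to 0.10, with 7 of these higher and 4 lower. The Gzmc to Gzmg genes are near-identical copies, so reads may have been split among them and the value of each alone is uncertain.

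Receptors shared with NK cells were mostly higher. In the authors' deposited table, 16 of 18 genes of the NK receptor list were higher, at a median log2 change of 1.38 (Fisher's exact test, adjusted p = 6.2e-04), and edgeR called 7 higher and 2 lower, or 17 in all when adjusted over the list alone. Klra5 rose by 3.92 (SE 0.54), Klra7 by 3.05 (SE 0.31) and Klra6 by 2.58 (SE 0.24), each with an edgeR adjusted p of 0.04. Tyrobp, the adaptor of activating receptors on NK and myeloid cells, fell by 1.13 (SE 0.18), and Fcgr3, an Fc receptor of the same cells, fell by 1.70 (SE 0.40). The Klra genes are a multigene family of similar sequence, and their separate values are uncertain for that reason. The list of NK cell markers had 13 of 15 members higher in the authors' deposited table (median 1.96, Fisher's exact test, adjusted p = 0.0029), with 9 called higher by edgeR and 1 lower. When scaled on the T cell receptor signalling genes, the medians were 0.28 for NK receptors (14 higher, 4 lower) and 0.82 for NK markers (11 higher, 4 lower). Of these 15 NK marker genes, 10 also belong to other lists, most to the NK receptor list and the rest to lists of T cell functions. The NK marker and NK receptor lists are therefore not separate evidence. Klra4 was lower, with a log2 change of -1.95 (SE 0.54) and an edgeR adjusted p of 0.061, and was called at -2.66 without treated library 1.

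Of the 28 genes listed for the IL-2 and IL-15 receptor pathway, 16 passed the authors' threshold, and these were mostly higher. In the authors' deposited table, 13 of 16 members were higher (median 0.98, Fisher's exact test, adjusted p = 0.0054), and edgeR called 7 higher and 2 lower, or 16 adjusted over the list alone. Socs1, a feedback inhibitor of cytokine signalling, rose by 1.32 (SE 0.16), and Xbp1 by 0.73 (SE 0.10), each with an edgeR adjusted p of 0.04. Osm, the cytokine oncostatin M, fell by 1.05 (SE 0.20) and Socs3 fell by 0.77 (SE 0.17), with edgeR adjusted p of 0.042 and 0.047. Il2rb, the receptor chain that binds both cytokines, went from 16774 ± 8847 to 48691 ± 7073 reads (SD, n = 3), a log2 change of 1.54 (SE 0.40) with an edgeR adjusted p of 0.056. Cish, a STAT5 target, stood at a log2 change of 1.39 (SE 0.39, edgeR adjusted p = 0.062). Scaled on the T cell receptor signalling genes, the median of the list turned to -0.34, with 6 members higher and 10 lower. Il2rg and Il15ra are outside the table.

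All 21 T cell receptor signalling genes present were higher in the authors' deposited table, at a median log2 change of 1.19 (Fisher's exact test, adjusted p = 1.3e-07). The edgeR fit called 0 of them, while 19 had an unadjusted p under 0.05, 18 passed when adjusted over the list alone, DESeq2 called 17 and limma-voom 14. Prkcq and Grap2, which relay the receptor signal, stood at log2 changes of 1.55 (SE 0.42) and 1.51 (SE 0.40), with edgeR adjusted p of 0.059 and 0.058. The list separated the PBS libraries too, with medians of -0.75, 0.73 and 0.04 in PBS libraries 1 to 3 against 1.06, 1.49 and 1.37 in the treated ones. Cd8b1, a chain of the sorted surface marker, varied with it, at 4546, 12330 and 6681 reads in PBS and 13357, 18056 and 14954 in treated libraries (log2 change 0.98, SE 0.38, edgeR adjusted p = 0.13). All 7 costimulatory receptor genes present were higher in the authors' deposited table (median 1.09, Fisher's exact test, adjusted p = 0.0058), of which edgeR called 1, Cd7, with a log2 change of 1.96 (SE 0.37); 5 passed adjusted over the list alone. Scaled on the T cell receptor signalling genes, the costimulatory median was -0.08. Cd8a and Cd3e are outside the table.

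Of the 25 inhibitory receptor and exhaustion genes listed, 8 were in the authors' deposited table, 7 of them higher (median 1.19, Fisher's exact test, adjusted p = 0.023). The edgeR fit called 2, or 8 adjusted over the list alone. Eomes, a transcription factor of effector and memory cells, rose by 2.08 (SE 0.30) and Batf by 1.30 (SE 0.28). Pdcd1, which encodes PD-1, the target of the antibody, went from 3874 ± 1712 to 8676 ± 1606 reads (SD, n = 3), a log2 change of 1.16 (SE 0.35) with an edgeR adjusted p of 0.072. Entpd2, which entered the list under its older symbol Cd39l1, is not itself an inhibitory receptor. It was lower, with a log2 change of -2.88 (SE 0.94, edgeR adjusted p = 0.082), and was called at -4.54 without treated library 1. The exhaustion median was 0.03 when scaled on the T cell receptor signalling genes.

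Stem-like and memory genes split, with 7 of 13 higher and 6 lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.48), and edgeR called 4 each way. The transcription factor genes Tcf7 and Lef1 rose by 1.14 (SE 0.14) and 1.85 (SE 0.28) on the log2 scale, while Bcl6 fell from 536 ± 64.4 to 189.9 ± 12.1 reads and Klf3 from 1340 ± 300.3 to 378 ± 175 reads (SD, n = 3). Scaled on the T cell receptor signalling genes, Tcf7 stood at -0.14 and the list's median at -0.60, with 3 genes higher and 10 lower. Terminal differentiation genes were 7 higher and 4 lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.29), with 2 called higher and 3 lower by edgeR. Relative to the T cell receptor signalling genes, 5 were higher and 6 lower. This was a larger share higher than among the other table genes (Fisher's exact test, adjusted p = 0.0078). Under that scaling the median log2 change of all fitted genes was -2.0. Txnip rose by 1.12 (SE 0.24), and of the transcription factor genes Zeb2 fell by 1.51 (SE 0.20) and Runx1 fell by 1.59 (SE 0.27). All 4 tissue residency genes present were higher in the authors' deposited table, too few for the list test; Cd69 was called by edgeR, with a rise of 2.00 (SE 0.39), and Itga1 stood at 1.43 (SE 0.45, edgeR adjusted p = 0.076).

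Chemokine receptor and migration genes were 11 higher and 6 lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.12), of which edgeR called 5 and 3. Relative to the T cell receptor signalling genes, 7 were higher and 10 lower, at a median of -0.18. This was a larger share higher than among the other table genes (Fisher's exact test, adjusted p = 0.0027). Cxcr3 and Cxcr4 rose by 2.01 (SE 0.34) and 1.49 (SE 0.27), while Cd44 fell by 0.67 (SE 0.11) and the gut-homing receptor gene Ccr9 fell by 2.70 (SE 0.58). T cell cytokine and chemokine genes were 7 higher and 7 lower in the authors' deposited table (adjusted p = 0.66 by Fisher's exact test), with 2 called each way by edgeR. The median changes sign with the genes fitted and with the scaling. Relative to the T cell receptor signalling genes, 6 were higher and 7 lower, again a larger share higher than among the other table genes (Fisher's exact test, adjusted p = 0.0029). Tnfsf11, the gene of RANKL, rose by 1.75 (SE 0.40), Ccl1 fell by 1.88 (SE 0.29) and Spp1, the gene of osteopontin, fell by 1.63 (SE 0.27). Ifng is outside the table. Pro-apoptotic genes were 6 higher and 1 lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.075), with 3 called higher and 1 lower by edgeR, and 2 were higher and 5 lower (median -0.45) relative to the T cell receptor signalling genes. Bax and Bcl2l11, the gene of BIM, rose by 0.92 (SE 0.13) and 1.27 (SE 0.29), and Trp53 fell by 0.77 (SE 0.16).

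All 63 cytosolic ribosomal protein genes present were higher in the authors' deposited table, between 0.34 and 0.91 on the log2 scale (Fisher's exact test, adjusted p = 5.3e-23), and edgeR called 47. Rpl3 rose from 22833 ± 2034 to 38144 ± 1162 reads and Rpl4 from 43338 ± 2506 to 67197 ± 2635 (SD, n = 3). All 38 oxidative phosphorylation genes present were higher in the authors' deposited table (median 0.52, Fisher's exact test, adjusted p = 7.7e-14), with 18 called by edgeR, among them the ATP synthase genes Atp5e at 0.75 (SE 0.11) and Atp5d at 0.66 (SE 0.10). All 10 fatty acid oxidation genes present were higher in the authors' deposited table (median 0.50, Fisher's exact test, adjusted p = 7.5e-04), and edgeR called 8. Cpt1a, which admits long-chain fatty acids to mitochondria, rose by 1.45 (SE 0.14) and the carnitine carrier gene Slc25a20 by 1.18 (SE 0.15). Scaled on the T cell receptor signalling genes, the medians of these 3 lists turned to -0.80, -0.87 and -0.86.

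Of the cell division lists, 10 of 44 DNA replication genes and 14 of 46 mitosis genes passed the authors' threshold, against 37.9% of all genes tested. The cell division genes that passed were mostly higher. All 10 DNA replication genes present (median 0.57, Fisher's exact test, adjusted p = 7.5e-04) and 12 of 14 mitosis genes (median 0.50, adjusted p = 0.0050) were higher in the authors' deposited table, and edgeR called 6 and 5 of these. Ccne1, the gene of cyclin E1, rose by 1.14 (SE 0.15) and Rpa2 by 0.66 (SE 0.11), while Nusap1 rose by 0.56 (SE 0.11). Anln, which encodes the cytokinesis protein anillin, fell by 1.89 (SE 0.44), and Pbk stood at -1.10 (SE 0.30, edgeR adjusted p = 0.061). Mki67, the gene of the proliferation marker Ki-67, stood at a log2 change of 0.63 (SE 0.20, edgeR adjusted p = 0.076). Scaled on the T cell receptor signalling genes, both medians turned negative, to -0.82 and -0.90.

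Other metabolic lists were mixed. Glycolysis genes were 4 higher and 4 lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.78), with 3 called higher and 1 lower by edgeR. Their median of -0.10 turned to 0.17 with TMM and 0.31 with median-ratio factors, and 1 was higher and 7 lower relative to the T cell receptor signalling genes. Gpi1 and Aldoa rose by 0.76 (SE 0.11) and 0.50 (SE 0.09), and Pfkm fell by 1.12 (SE 0.26). Amino acid and one-carbon genes were 5 higher and 3 lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.37), and edgeR called 3 higher and 1 lower; relative to the T cell receptor signalling genes, 1 was higher and 7 lower. Ddit4 rose by 1.52 (SE 0.16) and Chac1, a target of the amino acid stress response, fell by 2.32 (SE 0.49). Ribosome biogenesis genes were 4 higher and 5 lower in the authors' deposited table (Fisher's exact test, adjusted p = 1.0), and edgeR called 2, both higher; relative to the T cell receptor signalling genes, 0 were higher and 9 lower (median -1.82). In that list Npm3 rose by 0.78 (SE 0.11) and Ddx21 by 0.54 (SE 0.12), and Myc stood at -0.64 (SE 0.21, edgeR adjusted p = 0.081).

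All 8 MHC class II genes present were lower in the authors' deposited table, at a median log2 change of -2.48 (Fisher's exact test, adjusted p = 0.042), and edgeR called all 8. Of these genes, 4 are also on the dendritic cell list, so the lists are not separate evidence. Ciita, the master regulator of these genes, fell from 335 ± 40.6 to 66.8 ± 21.8 reads and H2-DMa from 1126 ± 63.6 to 440.0 ± 45.9 (SD, n = 3). MHC class I and interferon-gamma genes were 11 higher and 6 lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.12), with 6 called higher and 1 lower by edgeR. Relative to the T cell receptor signalling genes, 0 of these 17 were higher and 17 lower, and the median turned from 0.50 to -0.79. Psmb8, an immunoproteasome subunit gene, rose by 0.74 (SE 0.13), whereas the chemokine gene Cxcl9 fell by 3.05 (SE 0.48; -3.72 without treated library 1) and Cxcl10 stood at -1.58 (SE 0.42, edgeR adjusted p = 0.058). Type I interferon genes were 5 higher and 6 lower in the authors' deposited table (Fisher's exact test, adjusted p = 1.0), and edgeR called 1 each way, with 1 higher and 10 lower relative to the T cell receptor signalling genes. Oas3 rose by 0.93 (SE 0.22) and Ifih1 fell by 0.78 (SE 0.15), while Slfn1 stood at 1.39 (SE 0.35) and Oas2 at -1.96 (SE 0.51), with edgeR adjusted p of 0.052 and 0.055.

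Markers of other tumour cell types were lower in the treated libraries. In the authors' deposited table, 21 of 24 macrophage and monocyte genes (median -2.24, Fisher's exact test, adjusted p = 0.0066), 15 of 16 dendritic cell genes (median -2.47, adjusted p = 0.0075), 16 of 17 fibroblast and pericyte genes (median -3.22, adjusted p = 0.0054) and all 9 endothelial genes (median -2.84, adjusted p = 0.023) were lower. The edgeR fit called 18, 12, 3 and 4 of these lower. Csf1r, the macrophage growth factor receptor gene, fell from 2520 ± 459 to 393 ± 263 reads (log2 change -2.68, or -3.38 without treated library 1) and Cd14 from 2169 ± 479 to 461 ± 219 (SD, n = 3). H2-Ab1 fell by 2.56 (SE 0.40), Postn, the matrix protein periostin, fell by 3.09 (SE 0.62), and of the endothelial receptor genes Flt1 fell by 2.53 (SE 0.46) and Kdr fell by 3.37 (SE 0.69). Exceptions were the dendritic cell transcription factor gene Batf3, which rose by 2.13 (SE 0.37), and Ly6c2, Plac8, Ccr2 and Thy1, which T cells also express, at log2 changes of 1.53 (SE 0.40), 1.26 (SE 0.36), 1.19 (SE 0.41) and 1.11 (SE 0.38); Ccr2 was chosen after its values were seen. Treated library 1 kept more of the macrophage, dendritic and fibroblast RNA, with a macrophage median of -1.39 against -2.81 and -2.88 in treated libraries 2 and 3, and a fibroblast median of -2.01 against -4.79 and -4.46. The endothelial medians did not follow this, at -2.17, -3.05 and -2.03 in treated libraries 1 to 3.

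**Figure D2:**
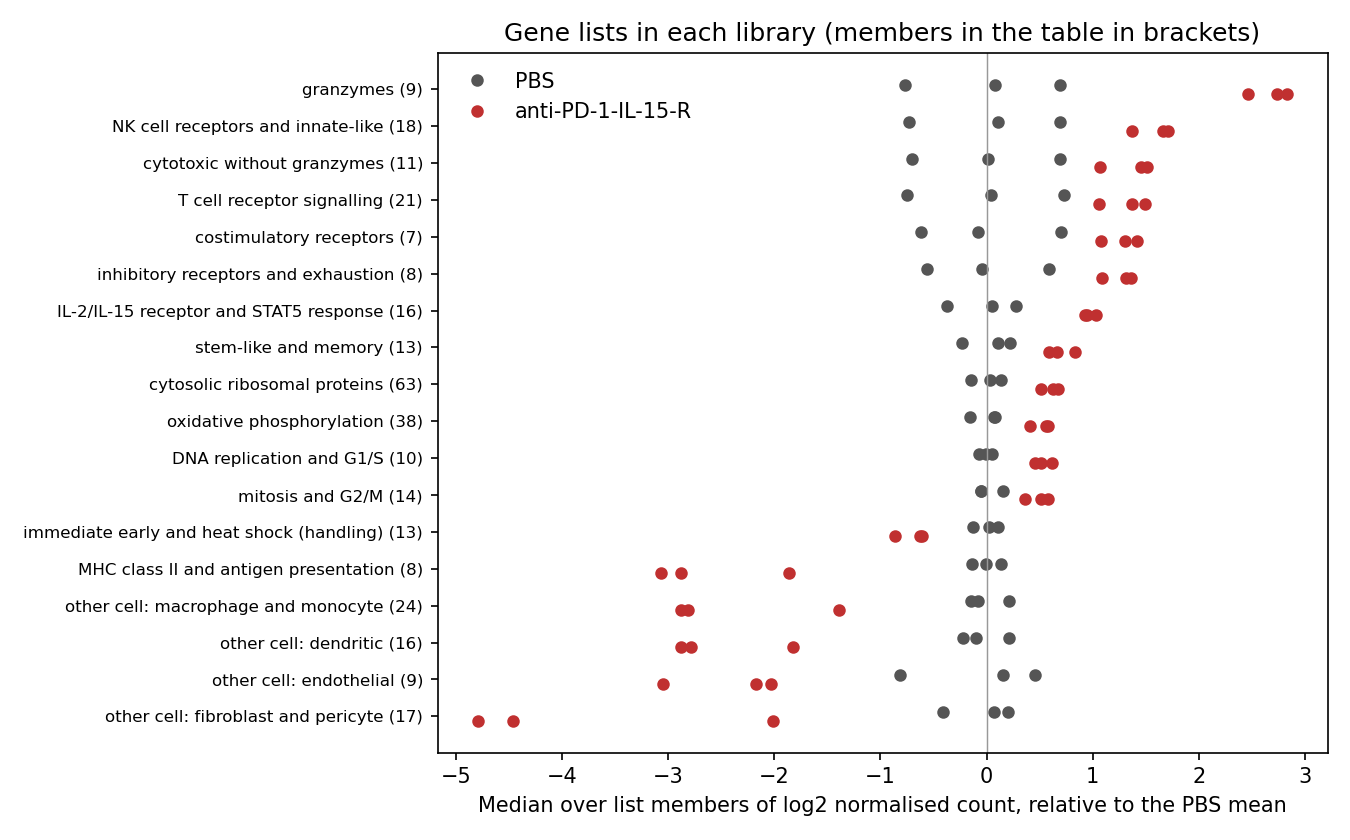
Median over the members of each gene list of the log2 normalised count relative to the PBS mean, 1 point per library, PBS in grey and αPD-1-IL-15-R in red. The granzyme medians of the treated libraries lay between 2.46 and 2.83, the T cell receptor signalling medians between 1.06 and 1.49, and the fibroblast medians between -4.79 and -2.01; scaled on the T cell receptor signalling genes, the medians of the ribosomal, respiratory, cell division, stem-like, costimulatory and IL-2/IL-15 lists, among those plotted, change sign.

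Other cell type lists were thinly represented. Of the tumour epithelial list, 4 of 5 genes were lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.48), with Itgb4 and Sox9 at log2 changes of -3.31 (SE 1.01) and -3.21 (SE 1.01) and Cdh1 at 0.72 (SE 0.21); edgeR called 0 of the 5, against 3 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 4 each. Of 4 neutrophil genes in the authors' deposited table, 3 were higher, among them S100a8 and S100a9, and Mmp9 was lower; edgeR called 0, against 4 at an unadjusted p under 0.05, 4 by DESeq2 and 1 by limma-voom. Of 4 CD4 and regulatory T cell genes, Lrrc32 rose by 1.48 (SE 0.26), Il2ra stood at 1.34 (SE 0.40) and Zbtb7b, a CD4 lineage factor gene, at -0.29 (SE 0.10); Zbtb7b turned to 0.13 with median-ratio scaling. All 3 gamma-delta T cell genes present were lower in the authors' deposited table. Ebf1, the only gene present of the 16 on the B and plasma cell list, stood at -3.04 (SE 0.92, edgeR adjusted p = 0.071). The basophil and mast cell list gene Gata2 stood at -3.10 (SE 0.87, edgeR adjusted p = 0.063), and the erythroid list gene Car2 rose by 1.57 (SE 0.34). Without treated library 1, the log2 changes were -5.13 for Itgb4, -5.04 for Sox9, -4.72 for Ebf1 and -4.64 for Gata2, and edgeR called all 4. Mcpt8 was read too little for the edgeR fit, at 1.9 ± 1.7 and 10.6 ± 4.1 reads in PBS and treated libraries (SD, n = 3).

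Of the genes that respond to tissue handling, 11 of 13 were lower in the authors' deposited table (Fisher's exact test, adjusted p = 0.082), and edgeR called 6 of these. The same test gave an adjusted p of 0.046 with median-ratio factors and 0.047 with a mean of at least 5 CPM. Of the heat-shock genes, Hspa1b fell by 2.06 (SE 0.26) and Hsph1 fell by 1.05 (SE 0.18), while Jund rose by 0.70 (SE 0.14) and Btg2 stood at 1.12 (SE 0.32, edgeR adjusted p = 0.065). Genes of the mitochondrial genome are outside the table.

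The authors marked 34 genes of their table as effector, stem-like or exhausted, a choice made on these samples, so its directions are not independent evidence, and the examples below were chosen after their values were seen. In the authors' deposited table, 22 of the 24 genes marked effector were higher, among them Bcl2 at a log2 change of 2.15, Prf1 at 1.39 and Tnf at 1.33, and Cx3cr1 and Il18 were lower at -1.20 and -2.06. The authors' deposited table marked 9 genes as stem-like, 5 higher and 4 lower, with Gzmk at 2.03 and Cd28 at 1.04 among the higher and Id3 at -1.29 and Ccr6 at -3.87 among the lower. The 1 gene marked exhausted, Tbx21, stood at 1.07 in the authors' deposited table. Outside that selection, the notes sheet beside the authors' deposited table lists the inhibitory receptor gene Havcr2 at a log2 change of 0.99 with a q-value of 0.06 and Stat5a at 0.52 with a q-value of 0.07.

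Over the 6251 genes fitted, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2327, of which 1031 were higher and 1296 lower, the smallest adjusted p being 0.04. DESeq2 called 6122 and limma-voom 4737 of the same genes. The number of calls depended on single libraries: it was 4549 without treated library 1 and 3018 without PBS library 2, and without PBS library 1, PBS library 3, treated library 2 or treated library 3, edgeR called 0 genes, although 4884, 4220, 4397 and 4305 genes had an unadjusted p under 0.05. The share of calls that were higher, 44.3%, was 21.9% with scaling by library size only, 57.3% with median-ratio factors of the table's genes and 62.8% with TMM over them, which moved the median log2 change by -0.14, 0.41 and 0.26. Scaling on the T cell receptor signalling genes moved it by -1.36 and turned 764 of the 2327 called genes the other way; edgeR then called 0, against 4063 at an unadjusted p under 0.05.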

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

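The scaling by TMM over the table's genes, the scaling on the T cell receptor signalling genes and the adjustment over the table's genes only were chosen after the data were seen, as were the authors' scaling of the reported fit, its use in DESeq2 and limma-voom, and the list test; the other alternatives were planned. The planned set tests (camera with a preset or an estimated correlation, and fry) were not run, because they need genes outside the selection, and those for normalised values alone do not apply to counts. The edgeR fit called 2327 genes, 1031 higher and 1296 lower. By test, DESeq2 called 6122 (2643 and 3479) and limma-voom 4737 (1889 and 2848). A mean of at least 5 CPM left 786 (403 and 383), no filter gave 2843, and adjustment over the table's genes only gave 6114 (2655 and 3459). By scaling, median-ratio factors gave 3944 (2258 higher), TMM 3177 (1995 higher) and library size only 2281 (500 higher). Testing against a fold of 1.5 gave 0 genes, 0 higher and 0 lower, in edgeR, against 3451 at an unadjusted p under 0.05. Scaling on the T cell receptor signalling genes gave 0 genes, 0 higher and 0 lower, against 4063 at an unadjusted p under 0.05. Leaving out 1 library gave between 0 and 4549 genes (0 to 1649 higher and 0 to 3040 lower). The count was 0 without PBS library 1, PBS library 3, treated library 2 or treated library 3, with 4884, 4220, 4397 and 4305 genes at an unadjusted p under 0.05, 3018 without PBS library 2 and 4549 without treated library 1. None of the 2327 genes changed direction in any of these 6 fits. The fits without 1 library have fewer samples; for the other changes the cause was not tested. Of 29 lists tested, 17 differed in direction from the other table genes, 17 or 18 under all alternatives run for the lists but scaling on the T cell receptor signalling genes, which gave 10. These 10 are not all among the 17. The terminal differentiation, T cell cytokine and chemokine receptor lists differed only under that scaling, each with a larger share higher than the other table genes. The ribosomal protein list turned, with 0 genes higher and 63 lower.

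With the sample number as a block, edgeR called 4337 genes (1743 higher and 2594 lower). Whether the numbers pair the libraries could not be decided. Across genes, which are not independent, the deviations from the group mean correlated at 0.58, 0.57 and -0.18 for numbers 1 to 3. PBS libraries 1 and 2 correlated best with the treated library of their own number, but PBS library 3 correlated best with treated library 1 (0.26). With 3 libraries a group, the deviations within a group depend on each other, so these correlations cannot settle it.

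Of 126 named genes fitted, 28 turned the other way when scaled on the T cell receptor signalling genes, which takes the rise of those genes out of every value by construction. Their log2 changes became -0.61 for Xbp1, -0.0019 for Socs1, -0.14 for Tcf7, -0.13 for Txnip, -0.18 for Ccne1, -0.71 for Rpa2, -0.85 for Nusap1, -0.72 for Spc24, -0.30 for Oas3, -0.60 for Psmb8, -0.58 for Gpi1, -0.87 for Aldoa, -0.70 for Atp5d and -0.63 for Atp5e. They were -0.15 for Slc25a20, -0.83 for Shmt2, -0.62 for Npm3, -0.78 for Ddx21, -0.73 for Rpl4, -0.66 for Rpl3, -0.45 for Bax, -0.62 for Jund, -0.09 for Btg2, -0.57 for Cdh1, -0.04 for Thy1, -0.17 for Cd8b1, -0.02 for Pdcd1 and -0.68 for Mki67. Zbtb7b turned to 0.13 with median-ratio factors. With 3 libraries a group and 200 changed genes, the simulated fit recovered 1% of changes of 1 and 27% of changes of 2 on the log2 scale. Far more genes differed in the real libraries, so these shares do not carry over to the real fit. A named gene short of the threshold is still not shown to be unchanged.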

Other observations

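All tests in this part were chosen after the values they bear on had been seen. Set against the T cell receptor signalling genes of the same library, some gene lists that had risen together moved apart. The granzyme median exceeded the T cell list by 1.37 ± 0.03 in the treated libraries against -0.01 ± 0.04 in PBS (SD, n = 3), and the NK receptor median by 0.27 ± 0.05 against 0.02 ± 0.05 (SD, n = 3). For both, and for heat-shock and immediate early genes, which differed by -2.0, the groups did not overlap, with an exact permutation p of 0.10, the smallest that 3 against 3 libraries allow. The groups overlapped for inhibitory receptor genes, which differed by -0.05, and costimulatory genes, by -0.03; the sign of both turned without PBS library 1, to 0.06 and 0.03, and without treated library 2, to 0.02 and 0.04. They also overlapped for the IL-2 and IL-15 pathway, stem-like, mitosis and ribosomal lists, which differed by -0.32, -0.65, -0.84 and -0.71. These differences rested in part on PBS library 1, without which they were -0.12, -0.40, -0.39 and -0.26. The IL-2 and IL-15 value was -0.53 without PBS library 2 and -0.20 without treated library 2. In all, 31 lists were set against the T cell list, and the groups did not overlap for 19, among them oxidative phosphorylation at -0.78 and MHC class I at -0.80 (-0.37 and -0.47 without PBS library 1), type I interferon at -1.85 and T cell cytokines at -1.33, a median over 7 genes higher and 7 lower. For oxidative phosphorylation and MHC class I the groups nearly touched, with PBS library 2 at -0.64 and -0.54 and treated library 1 at -0.66 and -0.57. Chance gives 10% for genes not picked on these groups, but these were picked for a difference between them, and some lists share genes, so that share does not apply here.

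Genes of macrophages, dendritic cells, fibroblasts and endothelium were lower in the treated libraries, although the cells were sorted for CD8. Lyz2, an abundant macrophage transcript chosen after its values were seen, went from 15473 ± 1874 to 2972 ± 2090 reads and Fn1 from 19287 ± 3921 to 2308 ± 1636 (SD, n = 3). On average both had more reads than Cd8b1 in the PBS libraries, at 7852 ± 4022 reads (SD, n = 3). Reads are not corrected for transcript length, so this does not rank the RNA amounts of these genes. With that many reads of both, the sort had not kept out all RNA of other cells. The median change of the fibroblast list minus that of the macrophage list was -0.99 (permutation test over genes, p = 2.0e-05, the smallest 100000 permutations can give), though genes are not independent. This does not decide on a single dilution factor for all other cells. T cells also express some macrophage list genes, which can lessen the fall of that list, and the genes had been picked for a difference. Medians lay below -1 in each treated library for 4 of these 4 lists, which decides nothing about less RNA of other cell types in the treated libraries, because the genes had been picked for a difference. Whether the treatment altered the tumours' cells or the sorts differed in purity stays open and was not tested.

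Granzyme genes were higher in the treated libraries, and the genes weighed beside them here were chosen after their values were seen. Against a higher share of T cell RNA as the whole cause, the granzyme median rose by 1.38 more than the T cell list, with no overlap between the groups. That list is an uncertain gauge of the share. It held only the 21 of its 32 genes that had passed the authors' threshold, and their log2 changes ran from 0.58 to 1.55. Gzma, Gzmb, Gzmk and Gzmm, outside the Gzmc to Gzmg copies, had a median change 1.11 above the T cell list, from 0.52 for Gzmm to 2.38 for Gzma. Reads moved among the copies would leave these genes unchanged, so this value bears on them only and decides nothing about the copies. More NK cells stay open as an explanation, since the sort had not kept out all RNA of other cells. The median change of Ncr1, Klre1, Tyrobp and Fcer1g minus that of the granzymes was -1.54, with Ncr1 at 1.07 and Klre1 at 1.22. Macrophages, however, also express Tyrobp and Fcer1g. The NK marker list exceeded the T cell list by 0.64 ± 0.06 in treated libraries against 0.04 ± 0.10 in PBS (SD, n = 3). The cytotoxic genes other than granzymes differed from the T cell list by 0.04, but as they went both ways, a higher share of T cell RNA is neither excluded nor borne out for that part. More granzyme RNA per T cell was not tested and stays open too.

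Ribosomal protein genes, all 63 of them higher, may reflect a higher share of T cell RNA. Within the groups, the slope of the ribosomal median on the T cell list median was -0.04 (95% interval -0.43 to 0.34), against 0.46 between the groups. The interval holds 0.23, the bound set for this test, so a share effect and a change within the cells cannot be told apart with 6 libraries.

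Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many edgeR calls. It gave 2327, against at most 0 in the other splits, where at most 57 genes had an unadjusted p under 0.05. The splits are too few for a share under 0.05, and the table's genes had been picked on the real split.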
